A study of Mus musculus with 15 samples.

How the data were processed

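The series measured open chromatin and gene expression in neurons of mouse embryos at embryonic day 15.5. The embryos carried a Th-EGFP transgene, in which the regulatory sequence of tyrosine hydroxylase (Th), the rate-limiting enzyme of catecholamine synthesis, drives a green fluorescent protein. Per the labels' protocols, transgenic males were mated with Swiss Webster females, midbrain and forebrain were microdissected, tissue was pooled by litter and dissociated with papain, and EGFP-positive cells were collected by fluorescence-activated sorting. ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, used 50000 sorted cells per library, and RNA-seq used at least that number, per the labels' protocols. The groups were 3 midbrain and 3 forebrain ATAC libraries, 4 midbrain and 4 forebrain RNA libraries, and 1 deeper sequencing run of midbrain ATAC replicate 2. Groups and replicate numbers came from the sample titles. The deep run carries the number of midbrain replicate 2 and was never counted as a replicate.

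Each ATAC library came with its own peak list. Per the file headers, peaks were called with MACS2 2.1.1.20160309 on paired-end fragments, library by library, with no control, no local background, all fragments of the filtered alignment kept and a q cutoff of 0.05. Alignment with Bowtie2 2.2.5 to mm9, quality checks with FastQC 0.11.2 and the use of SAMtools are listed in the submitters' processing notes. The filters applied to the alignments and any shift of reads for the transposase are not given in the sources used here. The deposited lists give, per peak, the pileup signal at the summit, a −log10 p-value, a fold enrichment and a −log10 q-value, all as the authors' peak caller wrote them. The q-values were used here only to rank peaks within a list. Total fragments per library were read from the file headers. The last peak on chromosome 1 ended at position 197068604 in the lists, beyond the 195471971 bp of that chromosome in GRCm38, in 7 of 7 lists, so the coordinates were taken as mm9. The annotation at hand was GRCm38, coordinates were not converted between builds, and an mm9 annotation was not used here. The planned comparisons that need genes beside peaks were therefore left out, namely expression of genes with and without an open promoter, region-specific peaks against expression, and peaks at named loci including Snca.

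The deposited expression table gives RPKM values (reads scaled by gene length in kilobases and by library size) of 47266 genes in the 8 RNA libraries, as the authors computed them. The names of HISAT2 2.0.1 and featureCounts come from the submitters' processing notes, which list both mm9 and mm10 for these libraries without a role for either. Per the labels' protocols, total RNA was amplified with the Ovation RNA-Seq System V2. Whether counting used strand, how it treated reads shared by paralogs, and the gene lengths behind the RPKM are not given in the sources used here, so values of near-identical copies and of antisense genes that overlap others are uncertain. The table names 36835 genes, GENCODE M21 names were used for another 10282, and 149 had no symbol. Gene positions are GRCm38, from GENCODE M21. The number of columns with per-sample values that belong to none of the samples was 0.

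The RPKM values are not counts, but low values fell on whole multiples of a step. With gene lengths from GENCODE M21 and a tolerance of 0.1 read, 91.6% to 94.0% of the low values of a library came out whole, and 40283 genes (85.2%) came out whole in all 8 libraries. The step gave an RPKM denominator of 31.7, 36.0, 36.1 and 38.1 M reads for midbrain 1 to 4 and of 32.0, 36.7, 38.6 and 40.9 M for forebrain 1 to 4. At such a denominator a gene of 1 kilobase with a single read has an RPKM between 0.0245 and 0.0316, so values near this floor carry large counting error.

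Genes with an RPKM of at least 1 in at least 4 of the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(RPKM + 1), with region as the single term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. Calls are genes with an adjusted p below 0.05. Fold changes are midbrain over forebrain on the log2(RPKM + 1) scale, which understates changes of low genes. Standard deviations (SD) are over the 4 libraries of a region on the RPKM scale. The labels do not say that each library came from its own litter, so p-values measure the spread between these libraries, which may be partly technical. Gene lists were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists with at least 3 tested members), and again with an estimated correlation and with fry. The 23 lists covered dopamine synthesis and transport, midbrain dopamine transcription factors, telencephalic and olfactory interneuron transcription factors, hypothalamic and diencephalic transcription factors, cortical projection neuron markers, GABA synthesis and transport, glutamate transport, serotonergic, noradrenergic and cholinergic markers, midbrain GABA and glutamate neuron markers, hindbrain Hox genes, neuropeptides, axon guidance, familial Parkinson disease genes, radial glia, cell cycle, oligodendrocyte, microglia, endothelial and mural, erythroid and dissociation-induced immediate early genes, and sex-linked transcripts. The groups, tests, lists, alternatives, apart from those named below as added, and the rule for named genes were fixed before the data were examined.

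Named genes were Th, Slc6a3 and Snca; in each direction the 12 genes with the largest absolute fold change among called protein-coding genes whose 4 libraries of one region all lay above the 4 of the other, with a mean RPKM of at least 5 in the higher region and leaving out predicted genes; and from each list up to 4 called members with the largest change or, where fewer than 2 passed, up to 2 with the highest mean RPKM. Regions were named as the 5 widest called in midbrain only and in forebrain only; the part of the rule on regions at loci was left out with the annotation. Other genes named where a count of 5 or fewer is spelled out, and those in gene families and in the account of single libraries, were chosen after their values were seen.

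Peaks of the 6 standard ATAC libraries that overlapped by at least 1 bp were merged. A region was midbrain-only when called in 3 of 3 midbrain and 0 of 3 forebrain libraries, and forebrain-only in the reverse case. Library pairs were compared by the Jaccard index, the shared base pairs over the base pairs covered by either list. Differences between the groups of 3 were set beside the 10 splits of the 6 libraries, which cannot give a p below 0.1. Shares of peaks in the deep run have Wilson intervals at 95%, which cover counting error only.

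Replicate numbers are shared between regions. Over the tested genes, the correlation of deviations from the region means was 0.32, 0.20, 0.26 and 0.17 for the RNA pairs numbered 1 to 4, above 0.1 in every pair. Pairs of unequal number ran from -0.294 to 0.197. The highest of them, midbrain 3 with forebrain 4, lay above the pairs numbered 2 (0.196) and 4 (0.169). Each midbrain library still had its highest correlation with the forebrain library of its own number, so the values favor a pairing without settling it. It could be taken from the data only, since the labels say that tissue was pooled by litter but not that a number marks a litter. The fit without the pairing remained the main one, as fixed beforehand, and the fit with the number as a block was an alternative.

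Alternatives set beforehand were pseudocounts of 0.1 and 0.5, no filter on low values, an RPKM of at least 5, libraries rescaled to the same sum, quantile normalization, no trend, a minimum change of 1 on the log2 scale, the block, each library left out in turn, and for peaks the best-ranked peaks of each list, an equal number of peaks per library (22858), a wider minimum overlap, the deep run in place of the standard run, summits extended to 500 bp and chromosomes 1 to 19 and X. Added after the data were seen were a fit with voom on whole reads recovered from the RPKM steps, a fit without both libraries numbered 1, and a fit without midbrain 1, forebrain 1 and forebrain 4. Other tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

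The RNA test was tested on simulated data, 20 draws of 15255 genes with the means and spread of the real libraries and 200 changed genes. It recovered 75.5% of genes changed by 1 and 94.5% of genes changed by 2 on the log2 scale, with 5.43% of calls false, and made at most 0 calls when no gene was changed. In simulated peak lists of 1550 regions, 100 of 100 midbrain-only and 150 of 150 forebrain-only regions were found. Each simulated peak was present in every library meant to hold it, so full recovery was fixed in advance and checks the counting only. The RNA draws varied each gene independently and without pairs, so they do not measure false calls among correlated genes.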

Results

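Open chromatin and transcripts were profiled in Th-EGFP-positive neurons sorted from the midbrain and the forebrain of mouse embryos at E15.5 (embryonic day). There were 3 ATAC libraries and 4 RNA libraries per region and 1 deep ATAC run of midbrain replicate 2. The series title names enhancer variants at SNCA, the gene of the Parkinson-associated protein alpha-synuclein. The design sets Th-EGFP-positive neurons of the midbrain against those of the forebrain. The share of dopamine neurons in either sort was not measured here. RPKM denominators were 31.7, 36.0, 36.1 and 38.1 M reads (M, mega) in midbrain RNA libraries 1 to 4 and 32.0, 36.7, 38.6 and 40.9 M reads in forebrain RNA libraries 1 to 4. The ATAC libraries held 16.1, 20.6 and 10.6 M fragments in midbrain 1 to 3, 10.99, 12.3 and 14.4 M in forebrain 1 to 3, and 150.2 M in the deep run.

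The first comparison asked which transcripts differ between Th-EGFP neurons of the 2 regions. Of 15255 genes tested, 712 were higher and 385 lower in the midbrain libraries at an adjusted p below 0.05 (limma, n = 4 per region), and 222 and 153 of them changed by at least 1 on the log2 scale. The genes with the largest increases were Aldh1a1, Slc6a3, Cck, Chrna6, Tfap2b, Foxa1, Pax5, En2, Lmx1b, Ebf3, En1 and Kcnk9, with log2 fold changes from 6.75 for Aldh1a1 to 3.91 for Kcnk9. The genes with the largest decreases were Lhx8, Dlx5, Dlx1, Foxg1, Isl1, Six3, Dlx2, Dlx6, Arx, Ecel1, Nkx2-1 and Lhx6, from -4.29 for Lhx8 to -3.06 for Lhx6. Among called genes, 708 of the higher and 376 of the lower had all 4 libraries of one region above all 4 of the other. A call at this sample size largely requires such separation, so these counts add no support. Of the tested genes, 15.1% were separated in this way in either direction, against 2.86% by chance. Genes vary together, so the chance share can differ widely between splits of the libraries, and it was not counted for other splits. On the first principal component, with 44.8% of the variance, midbrain 1 scored -4.30, midbrain 2, 3 and 4 scored -25.7, -36.8 and -35.8, and forebrain 1 to 4 scored 35.9, 24.8, 21.8 and 20.2. The counts fell by over 1.5 times without midbrain 2 (397 higher, 226 lower), midbrain 3 (367, 204), midbrain 4 (389, 210), forebrain 2 (427, 204), forebrain 3 (439, 226) or forebrain 4 (399, 231). With libraries rescaled to the same sum, which moved the median of all genes to -0.12, the split was 441 higher and 384 lower, or 53.5% higher in place of 64.9%.

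**Figure D1:**
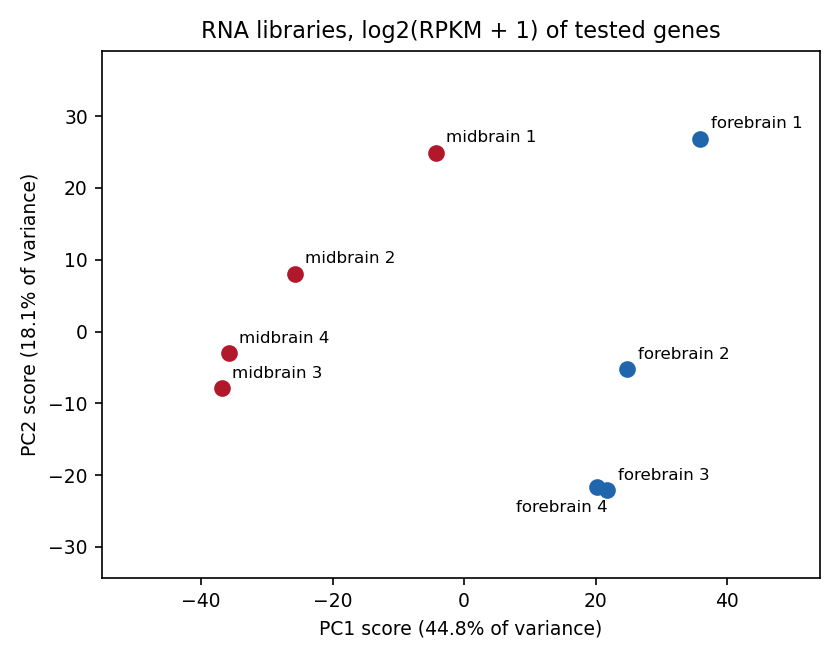
Scores of the 8 RNA libraries on the first and second principal components of log2(RPKM + 1) over the 15255 tested genes, with midbrain libraries in red and forebrain libraries in blue. Midbrain 1 lies at -4.30 on the first component, between midbrain 2 at -25.7 and the forebrain libraries at 20.2 to 35.9, and both libraries numbered 1 lie at the top of the second component, which holds 18.1% of the variance.

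Genes of dopamine synthesis and transport were higher in the midbrain, with Th, the rate-limiting enzyme of catecholamine synthesis, expressed in both regions. Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128 in GRCm38) reached 118 ± 48.3 RPKM (SD, n = 4) in midbrain and 22.7 ± 6.27 RPKM in forebrain neurons, a log2 fold change of 2.27 ± 0.31 (SE) with an adjusted p of 0.00367 (limma). Slc6a3 (ENSMUSG00000021609, chromosome 13, 73536747 to 73578672), the dopamine transporter, was at 73.6 ± 36.0 against 0.498 ± 0.327 RPKM, a change of 5.49 ± 0.39 with an adjusted p of 0.000165 (limma). Of 13 tested genes of dopamine synthesis and transport, 9 rose and 0 fell, and 11 rose when adjusted over the list alone (camera adjusted p = 7.06e-12; adjusted p = 0.103 with an estimated correlation). Aldh1a1, an aldehyde dehydrogenase that marks a subset of midbrain dopamine neurons, was at 183 ± 103 against 0.477 ± 0.437 RPKM. Ddc, which makes dopamine from L-DOPA, was at 51.5 ± 25.1 against 3.84 ± 1.65 RPKM, and Ret, a receptor for GDNF family ligands, at 15.9 ± 7.20 against 1.13 ± 0.315 RPKM. The 4 that did not pass were Pts, Qdpr, Maoa and Comt, with log2 fold changes of 0.22, 0.34, 0.23 and 0.19. Midbrain 1 had the lowest Th (64.2 RPKM), Slc6a3 (27.1 RPKM) and Aldh1a1 (50.6 RPKM) of the midbrain libraries. Without forebrain 4 the forebrain mean of Aldh1a1 was 0.263 RPKM.

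Transcription factors that specify midbrain dopamine neurons were higher in the midbrain as a group. Of 16 tested, 14 rose and 0 fell, and 15 rose when adjusted over the list alone (camera adjusted p = 3.19e-21; adjusted p = 0.103 with an estimated correlation). Foxa1 was at 28.4 ± 16.3 RPKM in midbrain and 0.248 ± 0.252 in forebrain neurons, and En2, a homeobox gene of the midbrain and anterior hindbrain, at 19.3 ± 6.00 against 0.0364 ± 0.0307 RPKM, with a change of 4.23 ± 0.21 and an adjusted p of 3.73e-05 (limma). En1 was at 16.4 ± 7.90 against 0.0215 ± 0.0243 RPKM and Lmx1b at 22.1 ± 11.2 against 0.268 ± 0.158 RPKM. Ebf3 was at 262 ± 62.9 against 16.1 ± 5.33 RPKM. Sox6 and Satb1 did not pass, with log2 fold changes of -0.20 and 0.28. Without forebrain 4 the forebrain means of Foxa1 and En1 were 0.123 and 0.010 RPKM.

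**Figure D2:**
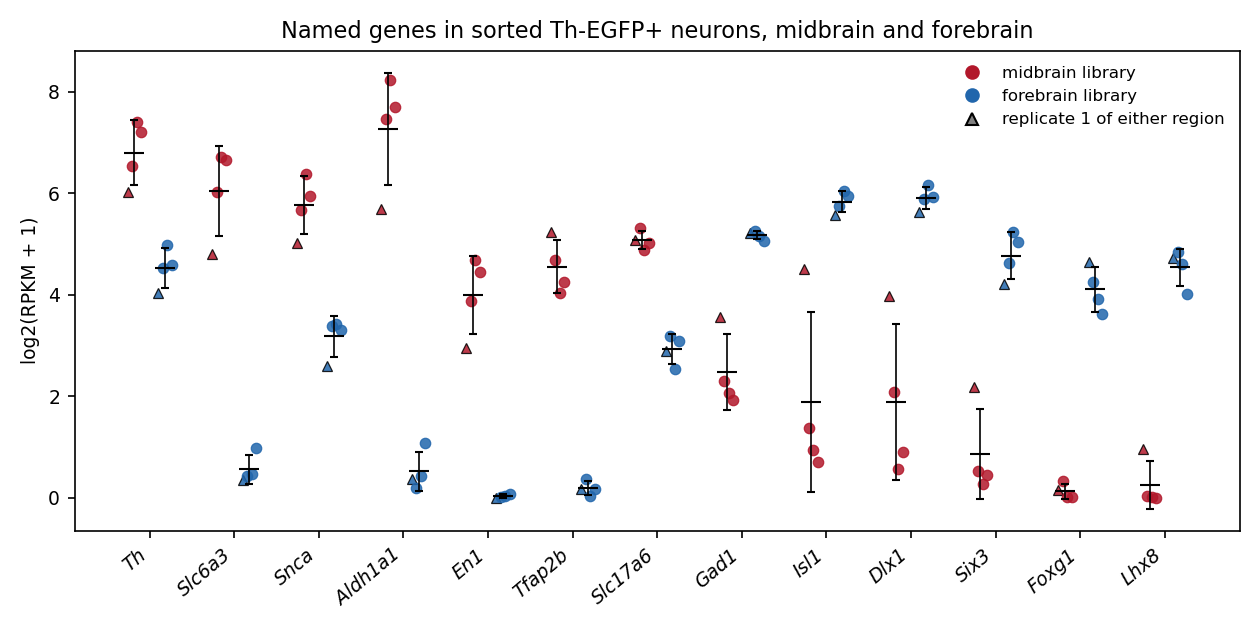
Expression of 13 genes as log2(RPKM + 1) in each of the 4 midbrain (red) and 4 forebrain (blue) RNA libraries, with the mean and SD in black and the libraries numbered 1 drawn as triangles. Th is at 118 RPKM in midbrain against 22.7 in forebrain, Slc6a3 and Aldh1a1 are below 0.5 RPKM on average in forebrain, and midbrain 1 holds 21.7 RPKM of Isl1 and 0.105 RPKM of Foxg1.

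Transcription factors of the telencephalon and of olfactory bulb interneurons were lower in the midbrain. Of 19 tested, 15 fell and 1 rose, and 16 fell when adjusted over the list alone (camera adjusted p = 1.21e-15; adjusted p = 0.114 with an estimated correlation). Foxg1, a regulator of the telencephalon, was at 0.0956 ± 0.117 RPKM in midbrain and 16.9 ± 5.52 in forebrain neurons, a change of -3.98 ± 0.21 (adjusted p = 3.73e-05, limma). Dlx1, a homeobox gene of forebrain GABA neurons, was at 4.83 ± 6.71 against 59.3 ± 9.18 RPKM, Dlx5 at 2.54 ± 3.27 against 43.6 ± 8.64 RPKM, and Dlx2 at 1.90 ± 2.44 against 23.8 ± 4.32 RPKM. The member that rose was Lhx2, at 16.5 ± 6.29 against 3.72 ± 1.14 RPKM. Midbrain 1 carried more of several of these transcripts than the other midbrain libraries, with 14.7 RPKM of Dlx1 and 7.26 RPKM of Dlx5, though 0.105 RPKM of Foxg1. Without midbrain 1 the midbrain means of Dlx1, Dlx5 and Dlx2 were 1.53, 0.963 and 0.701 RPKM, and without midbrain 2 that of Foxg1 was 0.0416 RPKM.

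Transcription factors on the list named for the hypothalamus and diencephalon were lower in the midbrain, and so were genes of GABA synthesis and transport. The list name does not mean that its members are confined to those parts of the forebrain. Of 14 tested hypothalamic and diencephalic factors 8 fell and 1 rose, counts that were the same when adjusted over the list alone (camera adjusted p = 2.08e-06; adjusted p = 0.268 with an estimated correlation). Lhx8 was at 0.242 ± 0.462 against 22.8 ± 5.39 RPKM, Six3 at 1.14 ± 1.59 against 27.3 ± 8.46 RPKM, Isl1 at 6.21 ± 10.3 against 56.2 ± 8.10 RPKM and Fezf1 at 0.247 ± 0.40 against 3.71 ± 0.954 RPKM. The member that rose was Nhlh2, at 7.22 ± 1.23 against 1.32 ± 0.242 RPKM. In GABA synthesis and transport, 5 of 5 genes fell, also when adjusted over the list alone (camera adjusted p = 2.23e-08; adjusted p = 0.103 with an estimated correlation). Gad1 and Gad2, the enzymes that make GABA, were at 5.21 ± 3.80 against 35.2 ± 2.1 RPKM and at 29.8 ± 15.2 against 152 ± 8.31 RPKM, Slc32a1, the vesicular GABA transporter, at 6.03 ± 2.13 against 23.3 ± 8.00 RPKM, and Abat at 4.67 ± 1.91 against 15.2 ± 1.72 RPKM. Midbrain 1 was the highest midbrain library for Isl1 (21.7 RPKM), Six3 (3.52 RPKM), Lhx8 (0.936 RPKM), Fezf1 (0.839 RPKM), Gad1 (10.9 RPKM) and Gad2 (52.6 RPKM). Without it the midbrain means were 1.05 for Isl1, 0.343 for Six3, 0.0110 for Lhx8, 0.0499 for Fezf1 and 3.32 RPKM for Gad1. Without midbrain 1 the counts over all genes were 1005 higher and 529 lower, and without midbrain 1, forebrain 1 and forebrain 4, an alternative added after the data were seen, they were 583 and 357.

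Markers of GABA and glutamate neurons of the midbrain were also higher in the sorted midbrain neurons. Of 6 tested, 6 rose, also when adjusted over the list alone (camera adjusted p = 5.06e-10; adjusted p = 0.103 with an estimated correlation). Tfap2b was at 23.7 ± 9.43 against 0.141 ± 0.109 RPKM, Lhx9 at 13.1 ± 4.66 against 1.30 ± 0.492 RPKM, Barhl2 at 10.47 ± 3.01 against 2.04 ± 0.702 RPKM and Pax7, a factor of the dorsal midbrain, at 3.08 ± 1.66 against 0.0408 ± 0.0455 RPKM, with midbrain 1 the highest of the midbrain libraries for Pax7 (5.57 RPKM). Without forebrain 2 the forebrain mean of Tfap2b was 0.0918 RPKM, and without forebrain 1 that of Pax7 was 0.0188 RPKM. Slc17a6, the vesicular glutamate transporter of subcortical neurons, was at 32.9 ± 4.26 against 6.71 ± 1.46 RPKM, a change of 2.15 ± 0.15 (adjusted p = 0.000165, limma). The other tested gene of glutamate transport, Gls, was at 18.8 ± 0.335 against 17.6 ± 1.39 RPKM and did not pass (adjusted p = 0.510, limma), and Slc17a8 was at 0.176 ± 0.0921 against 0.201 ± 0.0172 RPKM.

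Markers of cortical projection neurons moved both ways. Of 9 tested, Tbr1, Satb2 and Tle4 fell and Bhlhe22 rose, and 3 fell and 5 rose when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.868, ranked higher), its median log2 fold change was 0.37 and its mean -0.06. Tbr1 was at 0.60 ± 0.261 against 5.32 ± 0.633 RPKM, Satb2 at 0.932 ± 0.574 against 5.01 ± 1.64 RPKM, Tle4 at 16.1 ± 2.91 against 34.2 ± 5.11 RPKM, and Bhlhe22 at 1.78 ± 0.159 against 0.888 ± 0.224 RPKM (adjusted p = 0.0260, limma). The number that rose was 0 without midbrain 3, midbrain 4, forebrain 2, forebrain 3 or forebrain 4, with no filter on low values and with rescaled libraries (adjusted p of Bhlhe22 from 0.0711 to 0.122, limma). It was 3 without forebrain 1 and without both libraries numbered 1, and 2 by voom (of 8) and with the replicate number as a block. Without midbrain 1, forebrain 1 and forebrain 4 it was 2, and Bhlhe22 did not pass (adjusted p = 0.0683, limma).

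Markers of serotonergic, noradrenergic and cholinergic neurons and hindbrain Hox genes were too low to test, apart from Isl1. Isl1, held by the cholinergic list and by the hypothalamic one, fell, with a change of -3.95 ± 0.74 (adjusted p = 0.0145, limma). Htr1a, a serotonin receptor, was at 0.892 ± 0.108 RPKM in midbrain and 0.952 ± 0.133 in forebrain neurons, and Maob at 0.602 ± 0.285 against 0.228 ± 0.0495 RPKM. Pnmt was at 0.0719 ± 0.0852 against 0.399 ± 0.258 RPKM, Phox2b at 0.407 ± 0.217 against 0.0189 ± 0.0333 RPKM, Slc5a7 at 1.17 ± 0.659 against 0.398 ± 0.0727 RPKM and Slc18a3 at 0.464 ± 0.207 against 0.492 ± 0.159 RPKM. Hoxa2 was at 0.0712 ± 0.142 against 0.0167 ± 0.0250 RPKM and Hoxc5 at 0.00724 ± 0.00968 against 0.0622 ± 0.114 RPKM. Without midbrain 1 the midbrain means of Isl1, Pnmt, Hoxa2 and Hoxc5 were 1.05, 0.0321, 0 and 0.00283 RPKM, and without forebrain 1 the forebrain means of Phox2b, Hoxa2 and Hoxc5 were 0.00237, 0.00459 and 0.00528 RPKM.

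Neuropeptide genes split by region. Of 16 tested, Cck, Penk, Adcyap1 and Grp rose and Npy, Avp, Gnrh1 and Sst fell, and 4 rose and 6 fell when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.159). Cck, for cholecystokinin, was at 123 ± 66.0 RPKM in midbrain and 3.01 ± 1.24 in forebrain neurons, a change of 4.80 ± 0.43 (adjusted p = 0.000526, limma). Npy, for neuropeptide Y, was at 1.04 ± 0.655 against 14.8 ± 3.09 RPKM, Gnrh1, for gonadotropin-releasing hormone, at 1.71 ± 1.21 against 9.48 ± 2.39 RPKM, and Avp, for vasopressin, at 0.882 ± 1.64 against 9.84 ± 6.77 RPKM, with 3.34 RPKM in midbrain 1. The midbrain mean of Avp was 0.0624 RPKM without midbrain 1, and that of Gnrh1 1.11 RPKM without midbrain 4. The number that rose was 2 without midbrain 3, midbrain 4 or forebrain 4. The number that fell was 2 without midbrain 2, midbrain 3, midbrain 4, forebrain 2 or forebrain 4 and with the replicate number as a block. Avp did not pass in any of these fits, with adjusted p from 0.0658 with the block to 0.0968 without midbrain 3 (limma; 0.0321 with all libraries). Without both libraries numbered 1, 7 fell, and by voom 1 of 7 tested rose and 2 fell.

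Genes of axon guidance moved both ways as well. Of 39 tested, 7 rose and 8 fell, and 7 rose and 11 fell when adjusted over the list alone. The list did not pass (camera adjusted p = 0.553), and its median log2 fold change of 0.02 and mean of 0.05 were above 0 while camera ranked it lower. With rescaled libraries its median was -0.12 and its mean -0.08, and with quantile normalization -0.04 and 0.02. Ntn1, the guidance cue netrin, was at 33.6 ± 16.6 against 4.14 ± 1.54 RPKM and the chemokine receptor gene Cxcr4 at 5.33 ± 1.13 against 0.528 ± 0.359 RPKM. Sema3a was at 0.892 ± 0.539 against 3.64 ± 0.287 RPKM and Efnb2 at 7.58 ± 1.01 against 18.2 ± 0.990 RPKM. The number that rose was 4 without midbrain 3, midbrain 4, forebrain 3 or forebrain 4, and the number that fell was 5 without midbrain 2, midbrain 3, midbrain 4, forebrain 2, forebrain 3 or forebrain 4. With no filter on low values 4 rose and 5 fell, and with an RPKM of at least 5, 4 fell.

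Snca was higher in midbrain neurons. The gene (ENSMUSG00000025889, chromosome 6, 60731575 to 60829855 in GRCm38) was at 56.2 ± 21.3 RPKM in midbrain and 8.29 ± 2.21 RPKM in forebrain neurons, 6.78-fold on the RPKM scale and 2.58 ± 0.29 on the log2 scale, with an adjusted p of 0.00149 (limma) and 4 of 4 midbrain libraries above all forebrain libraries. Among 18 tested members of the list named for familial Parkinson disease, Snca, Dnajc6, Mapt and Uchl1 rose and 0 fell, and 4 rose when adjusted over the list alone. The name is that of the list, and a causal role of each member in familial disease was not checked. Dnajc6, a cofactor in the uncoating of clathrin-coated vesicles, was at 36.4 ± 8.43 against 18 ± 4.6 RPKM, the microtubule protein gene Mapt at 114 ± 16.8 against 70.0 ± 12.5 RPKM, and Uchl1 at 200 ± 26.5 against 123 ± 10.4 RPKM. The list passed with a camera adjusted p of 0.0290, though its median log2 fold change was 0.08 (-0.05 with rescaled libraries), and it did not pass with an estimated correlation (adjusted p = 0.321 with an estimated correlation), with rescaled libraries (camera adjusted p = 0.0529), quantile normalization (0.0603), without forebrain 1 (0.0819), without both libraries numbered 1 (0.0550) or without midbrain 1, forebrain 1 and forebrain 4 (0.0601). The adjusted p ranged from 0.00153 to 0.0468 over the remaining alternatives (camera or fry). The number that rose was 2 without midbrain 2, midbrain 3, midbrain 4, forebrain 2, forebrain 3 or forebrain 4 and with no filter on low values, fits in which Dnajc6 and Mapt did not pass (adjusted p of Dnajc6 from 0.0592 to 0.108 and of Mapt from 0.0573 to 0.0999, limma).

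**Figure D3:**
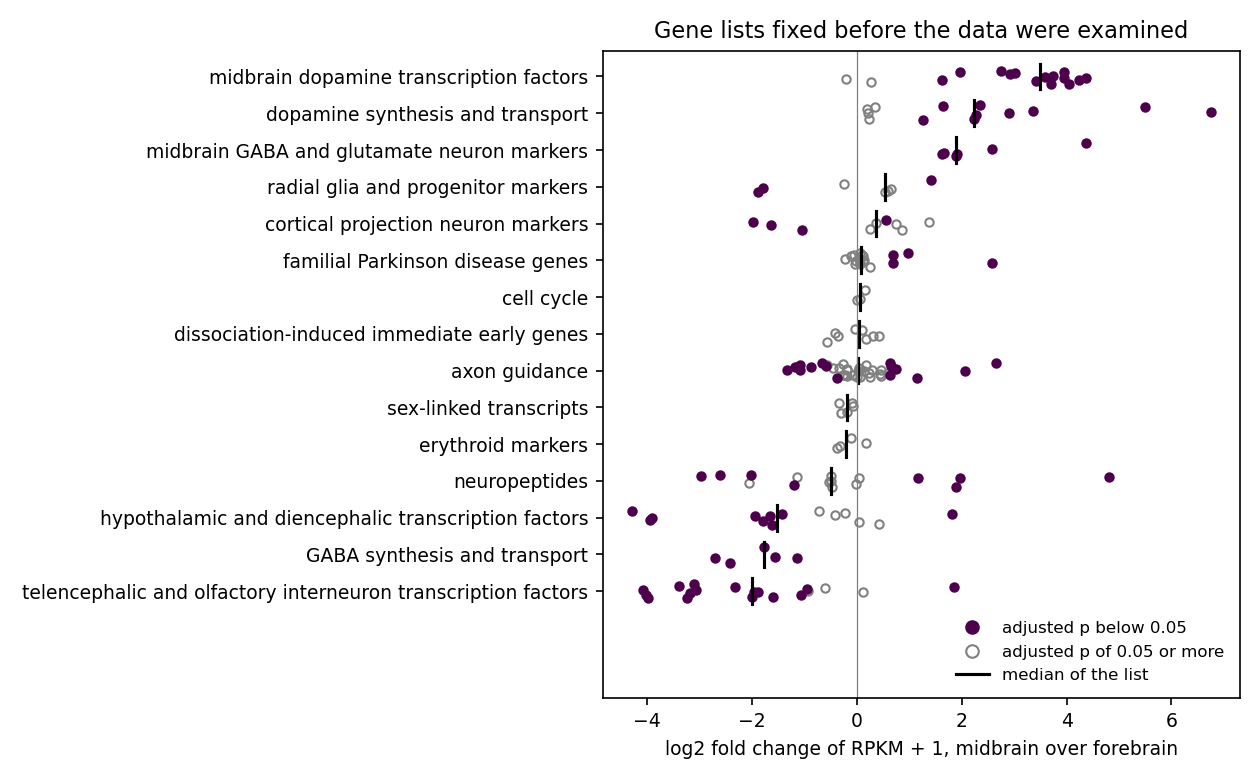
Log2 fold change of RPKM + 1, midbrain over forebrain, for each tested member of the 15 gene lists with at least 3 tested members, filled where the adjusted p (limma) is below 0.05 and open otherwise, with the list median as a black bar. The lists run from midbrain dopamine transcription factors, where 14 of 16 rose, to telencephalic and olfactory interneuron transcription factors, where 15 of 19 fell, and members of the axon guidance and neuropeptide lists lie on both sides of 0.

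Markers of other cell types were tested where they were abundant enough. Of 7 tested radial glia markers, Pax6 and Sox2 fell and Slc1a2, a glutamate transporter gene, rose, and 2 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.868, ranked lower, with a median log2 fold change of 0.54 and a mean of -0.10). Pax6 was at 0.842 ± 0.672 against 5.57 ± 0.543 RPKM, Sox2 at 0.969 ± 1.36 against 4.96 ± 1.30 RPKM, and Slc1a2 at 51.9 ± 21.5 against 18 ± 3.24 RPKM. Midbrain 1 held the highest midbrain values of Pax6 (1.85 RPKM) and Sox2 (2.98 RPKM), whose midbrain means were 0.506 and 0.30 RPKM without it. The number that fell was 1 without midbrain 2, midbrain 3, midbrain 4, forebrain 1, forebrain 2, forebrain 3 or forebrain 4, with a pseudocount of 0.1 and with no filter on low values, fits in which Sox2 did not pass (adjusted p from 0.0507 to 0.0827, limma; 0.0274 with all libraries), and the number that rose was 2 without forebrain 1, without both libraries numbered 1 and with the replicate number as a block. Of 3 tested cell cycle genes 0 were called by limma, with 0 at an unadjusted p below 0.05, and 0 of the 1 tested by voom. Pcna was at 9.08 ± 1.80 against 8.68 ± 2.08 RPKM and Ccnb2 at 2.18 ± 1.58 against 1.69 ± 0.529 RPKM, or 1.42 against 1.69 RPKM without midbrain 2 (camera adjusted p = 0.868). Of 4 erythroid markers, 0 were called by limma, 0 of 3 by voom, and 0 had an unadjusted p below 0.05 (camera adjusted p = 0.736), with Hbb-bs at 3.05 ± 2.51 against 3.56 ± 1.18 RPKM and Alas2 at 2.41 ± 1.19 against 3.28 ± 1.63 RPKM. The oligodendrocyte markers Mbp (2.89 ± 0.251 against 3.84 ± 0.797 RPKM) and Plp1 (0.955 ± 0.188 against 1.52 ± 0.352 RPKM) were not called over all genes by limma, nor Plp1 by voom, which did not test Mbp. When adjusted over the list alone, 2 of 2 fell, each with an unadjusted p below 0.05. No microglia or endothelial marker was abundant enough to test, with Aif1 at 0.472 ± 0.243 against 0.378 ± 0.159, P2ry12 at 0.410 ± 0.215 against 0.394 ± 0.222, Rgs5 at 0.464 ± 0.692 against 0.770 ± 0.608 and Pecam1 at 0.249 ± 0.0487 against 0.302 ± 0.151 RPKM. Rgs5 was at 0.118 RPKM in midbrain without midbrain 1 and 0.50 RPKM in forebrain without forebrain 3.

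Immediate early genes, which dissociation can induce, were abundant in both regions. Jun was at 25.1 ± 5.63 against 37.2 ± 4.91 RPKM and Dusp1 at 32.5 ± 3.13 against 42.0 ± 5.75 RPKM. Of 8 tested, 0 were called over all genes by limma, 1 of 6 fell by voom, and 2 rose and 3 fell both at an unadjusted p below 0.05 and when adjusted over the list alone (camera adjusted p = 0.868, ranked lower, with a median log2 fold change of 0.04 and a mean of -0.04). Over all genes, 1 fell with quantile normalization, without midbrain 1 and without midbrain 1, forebrain 1 and forebrain 4, and 1 rose without forebrain 1. With the replicate number as a block, and without both libraries numbered 1, 1 rose and 2 fell. Of 5 sex-linked transcripts, 0 were called by limma, 0 of 4 by voom, and 1, Kdm5d, had an unadjusted p below 0.05 (camera adjusted p = 0.189). Xist was at 94.3 ± 28.9 against 99.7 ± 27.9 RPKM and Eif2s3y at 9.47 ± 1.86 against 11.9 ± 2.53 RPKM.

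The second comparison asked which open regions belong to the neurons of one brain region. The 6 standard libraries gave 106344 merged regions, of which 16443 were called in all 6, with a median width of 1737 bp, and 43041 (40.5%) in a single library, with a median width of 425 bp. Regions called in 3 of 3 midbrain and 0 of 3 forebrain libraries numbered 477, and regions called in 3 of 3 forebrain and 0 of 3 midbrain libraries 1919. Midbrain 1 to 3 had 62646, 74018 and 22858 peaks, and forebrain 1 to 3 had 48525, 45222 and 52493 peaks. Midbrain 3, with the fewest peaks, bounds the midbrain-only count: without it 8814 regions were midbrain-only and 1964 forebrain-only. The forebrain-only count was 4099 without midbrain 1, 2921 without forebrain 1, 3101 without forebrain 2 and 2885 without forebrain 3.

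With the same number of best-ranked peaks taken from each library (22858), 361 regions were midbrain-only and 987 forebrain-only, 1348 in all. The other 9 splits of the 6 libraries gave at most 309 such regions in all, whereas with the full lists they gave up to 2369 against 2396 for the brain regions. With the best-ranked 1 in 2 peaks of each list, 2 of 10 splits gave as many (780 for the brain regions, highest other 1144), and with the deep run for midbrain 2, 3 of 10 did (1595, highest other 3131). The mean number of peaks was 53174 ± 26863 in midbrain and 48747 ± 3641 in forebrain libraries (SD, n = 3; exact permutation p = 0.9, two-sided, in a design that cannot give a p below 0.1).

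The widest midbrain-only regions, in mm9, were at 39253616 to 39256858 on chromosome 10, 15205655 to 15208566 on chromosome 6, 121200474 to 121203307 on chromosome 1, 87644507 to 87647213 on chromosome 16 and 63198589 to 63201229 on chromosome 17, with widths from 3243 to 2641 bp. The widest forebrain-only regions were at 60163109 to 60165586 on chromosome 4, 58478825 to 58481267 on chromosome 6, 25801927 to 25803957 on chromosome 11, 24986651 to 24988649 on chromosome 18 and 45702586 to 45704583 on chromosome 10, with widths from 2478 to 1998 bp. Genes at these positions are not given, since the annotation used here is of another build.

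Peak lists of the forebrain libraries overlapped each other most, with a mean Jaccard index of 0.585 over 3 pairs, against 0.413 over the 9 pairs between regions and 0.329 over the 3 midbrain pairs. Over both regions, pairs within a region averaged 0.457, a difference of 0.0442 from pairs between regions (exact permutation p = 0.1, one-sided, n = 3 per region, the smallest that 10 splits can give). The pairs ranged from 0.199 for midbrain 2 and midbrain 3 to 0.601 for forebrain 1 and forebrain 3, and the 5 pairs with midbrain 3 all lay at or below 0.319. Midbrain 3 had higher indices with forebrain 1 to 3 (0.291, 0.319 and 0.276) than with midbrain 1 (0.241) or midbrain 2 (0.199). List size also bounds the index: midbrain 3 covered 15.4 Mb, midbrain 1 and 2 58.2 and 70.2 Mb, and the forebrain libraries 40.6 to 49.2 Mb. Midbrain 1 had 0.548 with midbrain 2 and 0.534, 0.484 and 0.541 with forebrain 1 to 3. The difference was -0.0209 without forebrain 1, -0.0229 without forebrain 2, -0.0158 without forebrain 3, 0.129 without midbrain 1, 0.0914 without midbrain 2 and 0.104 without midbrain 3.

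**Figure D4:**
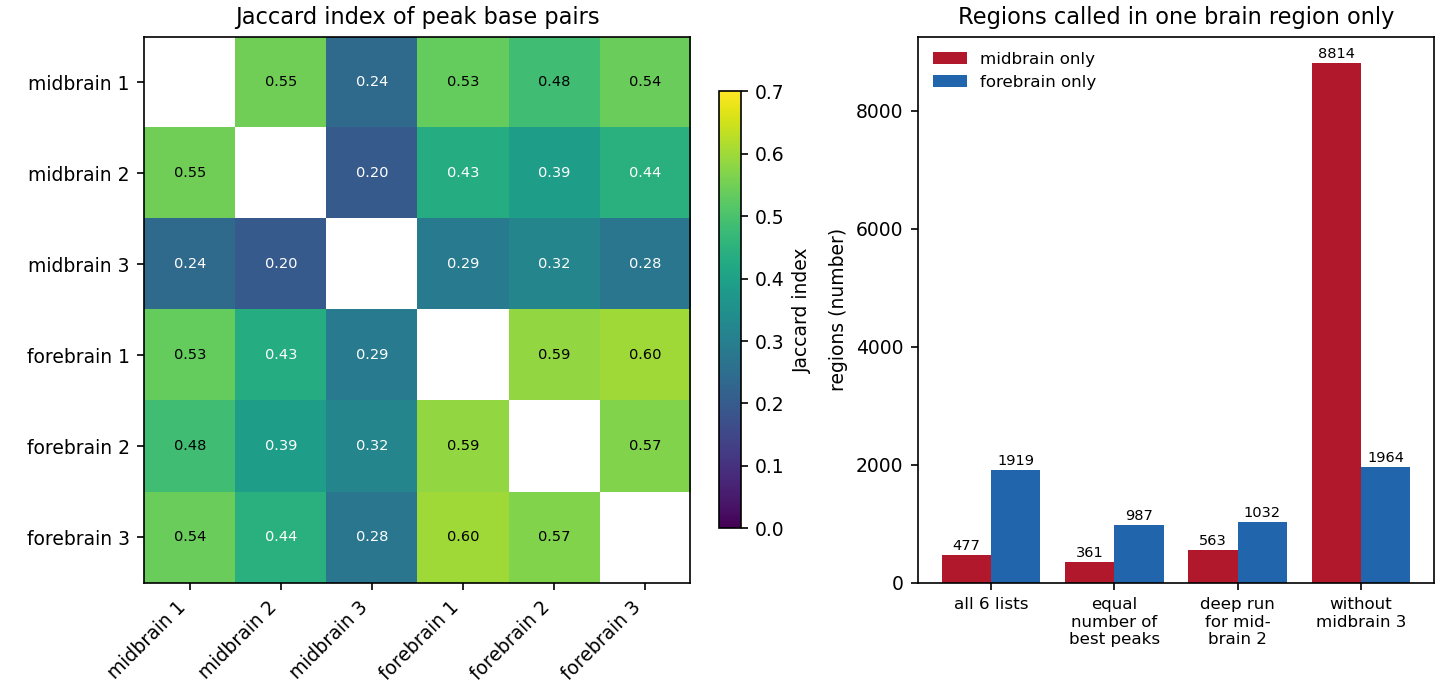
Left, Jaccard index of base pairs in peaks for each pair of the 6 standard ATAC libraries, on a color scale from 0 to 0.7. Right, numbers of midbrain-only (red) and forebrain-only (blue) regions with all 6 lists (477 and 1919), with 22858 best-ranked peaks per library (361 and 987), with the deep run for midbrain 2 (563 and 1032) and without midbrain 3 (8814 and 1964).

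The deep run asked how many open regions a standard run leaves uncalled. It held 187500 peaks against 74018 in the standard run of midbrain 2, from 150.2 against 20.6 M fragments. Of the standard peaks, 99.8% (Wilson 95% interval 99.77% to 99.84%) overlapped a deep peak, and 38.1% (37.9% to 38.4%) of the deep peaks overlapped a standard one. The deep list also covered 887 of 1919 (46.2%) forebrain-only regions, and with the deep run in place of the standard one 563 regions were midbrain-only and 1032 forebrain-only. Of the peaks of forebrain 1 to 3, 89.7%, 89.4% and 87.5% overlapped a deep midbrain peak, against 74.6%, 74.0% and 72.1% for the standard run. Per the file headers, the caller took a fragment size of 58 bp for the deep run, whereas its background depth corresponds to a mean of 275 bp, close to the 279 bp of the standard run.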

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

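For midbrain RNA library 1, all tests except that of background reads were chosen after the result was seen, as were the depth test on the number of genes above 0 and the depth and signal tests on midbrain ATAC library 3. Each named gene and some library measures were taken over the 4 RNA libraries of a region, 168 sets of values in all. In 20 sets a library had a gap to the nearest of the others of over 0.83 of the range. Midbrain 1 was that library in 15 of the 20, as the highest in 14 and the lowest in 1. Chance gives about 8.4 sets where values are normal, which RPKM values need not be. The sets share libraries and are not independent, so these counts only describe the values.

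Midbrain 1 held more of several transcripts that are high in the forebrain libraries, such as Isl1 at 21.7 RPKM (next midbrain library 1.60), Six3 at 3.52 (0.448), Arx at 3.32 (0.626), Lhx8 at 0.936 (0.0219), Gad1 at 10.9 (3.96) and Gad2 at 52.6 RPKM (24.0). The tables argue against a wrong label, since 48 midbrain-restricted transcripts kept a median of 44.0% of their level in midbrain 2 to 4, and against background reads spread over all genes, since 1413 silent receptor genes reached 0.762% of the median level of 40 forebrain-restricted transcripts there. They argue against cells like those of the forebrain libraries as the source of all its diencephalic transcription factors, since 4 of 43 factors (Otp at 31.4, Lhx1 at 13.6, Sox14 at 1.45 and Tbx3 at 1.33 RPKM, but not Isl1, Six3 or Lhx8) exceeded each other library by over 1.5 times, against at most 1 in any other library, whereas a blend lies between its sources. For the 40 transcripts such cells stay open, but the forms of the test disagree. A share is the excess over midbrain 2 to 4 relative to the forebrain mean. By level, 8 lay over 2 SD, scaled by the median share (19.5%), below what that share gives. Against this stood 9 in the forebrain library with the most, with the SD of the other forebrain libraries. That SD rests on fewer libraries than the SD over 4 used for midbrain 1, so the counts are not strictly alike. By share, 9 lay below 50% of the median share. In the forebrain library with the most, 6 lay below 50% of the mean of the others. Foxg1 was at 0.105 RPKM where the median share gives 3.39. Shares were also low for Lhx8 (4.05%), Npy (8.73%), Tbr1 (9.64%) and Lhx6 (10.2%), and high for Isl1 (36.7%) and Avp (33.3%). Hypothalamic or other diencephalic cells may be a source, since 6 of 18 such factors (Otp, Nkx2-4, Lhx1, Sox14, Tbx3 and Nhlh2, the last also higher in midbrain as a whole) were highest of the 8 libraries in midbrain 1 (chance 0.0186 if genes were independent) against 1 of 20 telencephalic ones, and a Th-EGFP sort would not remove those that express Th. The excess was not confined to such factors. Of the named markers of midbrain GABA and glutamate neurons, Tfap2b (36.6 RPKM), Barhl2 (14.2) and Pax7 (5.57) were also highest in midbrain 1. Lhx9 was not, at 13.4 RPKM against 19.6 in midbrain 2. A source among such midbrain neurons was not tested.

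More genes were above 0 in midbrain 1 (31769; next midbrain library 27528), forebrain 1 (36090) and forebrain 4 (34464) than in the other 5 libraries (at most 28023). Deeper sequencing is argued against, since 2 of the 3 had an RPKM denominator below the median of the 8. A low background of reads spread over all genes, from genomic DNA or unspliced RNA, stays open and may account for the pattern. Olfactory and vomeronasal receptor genes, silent in these neurons, averaged 0.0264, 0.0607 and 0.0317 RPKM in the 3 libraries and at most 0.0137 in the others, a ratio of 1.92 between the lowest of the 3 and the highest of the 5. Gm10800, a predicted gene, moved the same way, at 549 RPKM in midbrain 1 (next midbrain library 74.2), 1398 in forebrain 1 and 419 in forebrain 4, and no biological explanation was tested.

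Midbrain ATAC library 3 had 22858 peaks where the other standard libraries had 45222 to 74018, and a header fragment size of 195 bp where they had 283 to 303 bp, a difference not tested as a cause. Fewer fragments as the whole cause are argued against, since it had 2153 peaks per M fragments where the others had 3595 to 4414, a gap of 4.25 SD below the lowest. Weaker signal over background, so that mainly peaks that rank high elsewhere were called, stays open: 68.4% of its peaks overlapped the best-ranked 1 in 4 of the midbrain 2 peaks, against 65.9% to 67.5% for as many best peaks of the forebrain libraries and 71.9% for midbrain 1. Overlap with any midbrain 2 peak went the other way, at 87.1% of its peaks. The same number of best peaks gave 90.9% to 93.0% for the forebrain libraries and 98.7% for midbrain 1. This form of the signal test replaced an earlier one, set beforehand and met, because a short list is top-heavy by construction. Whether it holds open regions that the other libraries lack cannot be told, since 8.25% of its peaks overlapped no other standard library, within the 7.06% to 29.1% of the others.

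Further values set apart in midbrain 1 were Pax7 at 5.57 RPKM (next midbrain library 2.40), Avp at 3.34 (0.0961), Pax6 at 1.85 (0.525), Rgs5 at 1.5 (0.159), Fezf1 at 0.839 (0.138), Hoxa2 at 0.285 (listed at 0 in midbrain 2 to 4) and, as the lowest, Mapt at 88.7 RPKM (119). Htr1a was lowest in midbrain 3 at 0.731 RPKM (0.937) and Gnrh1 highest in midbrain 4 at 3.52 RPKM (1.23). Among forebrain libraries Slc6a3 was highest in forebrain 4 at 0.983 RPKM (0.383), and Phox2b and Hoxc5 in forebrain 1 at 0.0687 (0.00711) and 0.233 RPKM (0.0158).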

How the results depend on the processing

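The fits with voom, without both libraries numbered 1 and without midbrain 1, forebrain 1 and forebrain 4 were chosen after the data were seen. No gene called higher or lower changed sides in any of the fits. Of 54 called named genes 48 passed in all of up to 20 settings that tested them, while Sox2, Bhlhe22, Avp, Dnajc6, Mapt and Uchl1 were lost in 1 or more. Most named genes were picked for large called changes, which in part fixes this result. Of all 712 higher and 385 lower calls, 361 and 200 stayed without midbrain 3, and 383 and 223 with no filter on low values. The genes higher in midbrain numbered 712 and were 436 with no filter on low values, 454 with an RPKM of at least 5, 441 with rescaled libraries, 222 with a log2 fold change of at least 1, 1116 without both libraries numbered 1, and 367 to 1005 with a library left out. Genes lower in midbrain numbered 385 and were 241 with an RPKM of at least 5, 153 with a log2 fold change of at least 1, 718 without both libraries numbered 1, and 204 to 529 with a library left out. Fewer genes pass a required change, and fewer are tested at an RPKM of 5 (7664), by construction; for the others the cause was not tested. With the replicate number as a block, the paired fit, 993 were higher and 503 lower. Among named genes it ended the call on Avp and no other, and it ended or added no list call. Of all 35 splits of the 8 RNA libraries, 1, the real one, gave as many calls (1097, highest other 4). That share is under 0.05, but it counts against chance only if equal numbers are not paired. The 8 splits that, like the real one, part all 4 pairs of the same number are too few for a share under 0.05 (highest other 0); the other 27 part at most 2 pairs.

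Of the 15 list tests, 7 passed with the preset correlation and 0 of 15 with an estimated one, where 5 had an unadjusted p below 0.05 (camera). Apart from the estimated correlation, the calls on 6 of the 7 held in all alternatives. The call on the list named for familial Parkinson disease was lost in 6 of 22, the estimated correlation among them. Neuropeptides passed in 1, with an RPKM of at least 5 (adjusted p = 0.00682, camera). The alternatives with no trend and with a minimum change could not alter camera by construction, so they add no support. Lists that passed nowhere but changed direction were cortical markers (camera adjusted p = 0.966 with no filter; 0.380 to 0.986 with a library left out), radial glia (0.0711 with an RPKM of at least 5, 0.779 rescaled, 0.984 with quantile normalization, 0.750 with the block, 0.938 by voom; 0.315 to 0.977), cell cycle (0.406 with no filter; 0.672 to 0.977), erythroid markers (0.314 to 0.977) and immediate early genes (0.324 with no filter, 0.892 by voom). Genes not called that changed sign were Gls (-0.0390 rescaled), Pcna (-0.0620 rescaled, -0.0934 without midbrain 1, forebrain 1 and forebrain 4; -0.0530 to 0.20 with a library left out), Ccnb2 (-0.15 to 0.35) and Xist (-0.29 to 0.0624). The cause was not tested.

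Midbrain-only regions numbered 477 and were 91 with the best-ranked peaks of each list (1 in 2) and 563 to 8814 with a library left out. Forebrain-only regions numbered 1919 and were 689 with those best-ranked peaks, 987 with an equal number, 1032 with the deep run and 1964 to 4099 with a library left out. Fewer peaks or libraries change such counts by construction. The Jaccard difference was 0.0442 and ranged from -0.0229 to 0.129 with a library left out, below 0 without forebrain 1, 2 or 3. It has no value at the wider minimum overlap, at which 99.6% of standard peaks lay in the deep run. The 10 splits of the 6 ATAC libraries are too few for a share under 0.05; the real split, 1 of 10, gave 2396 region-only regions (highest other 2369) and a Jaccard difference of 0.0442 (highest other 0.0403). Other splits gave as much with the best-ranked 1 in 2 peaks (780 regions, highest other 1144; Jaccard difference 0.0411, highest other 0.0477; 2 of 10 splits for both) and, for regions, with the deep run (1595, highest other 3131; 3 of 10). The replicate block changes no peak count, and alternatives that need genes beside peaks were not run. The standard list held 38.1% of the deep peaks, but the lists also differ in the header's fragment size (58 against 283 bp), so what depth alone limits was not tested. RPKM values near 0.0245 to 0.0316 rest on single reads for a gene of 1 kilobase.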

Other observations

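The families below were chosen after the calls were seen, as were the tests on them; the tests were not rerun with a library left out. Of 32 gene families, 11 passed (camera) and 0 passed with an estimated correlation (lowest adjusted p = 0.307 with an estimated correlation; 5 had an unadjusted p below 0.05). Iroquois genes, homeobox regulators of regional identity, rose in 3 of 3 (camera adjusted p = 1.38e-05), with Irx2 at 5.92 ± 1.59 RPKM in midbrain and 0.357 ± 0.182 in forebrain neurons (SD, n = 4). All 4 Dlx genes, which the telencephalic list also holds, fell (camera adjusted p = 6.98e-06). Of Zic genes, zinc finger factors, 5 of 5 fell (camera adjusted p = 1.38e-05; 3 of 5 with rescaled libraries), with Zic1 at 3.59 ± 3.01 against 26.7 ± 9.30 RPKM (2.18 in midbrain without midbrain 1). Of 8 Sox genes, Sox1, Sox2 (also a radial glia marker), Sox5 and Sox11 fell and 0 rose (camera adjusted p = 0.000267), with Sox11 at 163 ± 22.0 against 273 ± 18.5 RPKM. Of 9 POU genes, Pou3f2 and, from the list of midbrain GABA and glutamate neuron markers, Pou4f1 and Pou4f2 rose and 0 fell (camera adjusted p = 0.0458; 2 rose with rescaled libraries).

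Of 9 nicotinic acetylcholine receptor subunits, Chrna6, Chrnb3 and Chrna5 rose (camera adjusted p = 0.0168), with Chrnb3 at 12.2 ± 6.47 against 0.102 ± 0.120 RPKM (0.0450 in forebrain without forebrain 4). Of 13 synaptotagmins, calcium sensors of vesicle release and their relatives, Syt4, Syt7, Syt9, Syt13 and Syt17 rose (camera adjusted p = 0.00532; 4 with rescaled libraries), with Syt4 at 103 ± 22.2 against 35.1 ± 2.66 RPKM. Sodium channel subunits rose in 4 of 7 (Scn1a, Scn2b, Scn3b and Scn9a; camera adjusted p = 0.00952; 1 of 7 with rescaled libraries). Cadherins rose in 4 of 15 (Cdh7, Cdh9, Cdh11 and Cdh13; camera adjusted p = 0.0168). Tubulins rose in 8 of 11 (camera adjusted p = 3.90e-06), in 2 with rescaled libraries and 5 with quantile normalization, with Tuba1a at 2270 ± 124 against 1533 ± 104 RPKM. Complex I subunits rose in 2 of 36 (camera adjusted p = 0.000927), with a median log2 fold change of 0.15, or 0.02 with rescaled libraries, where 0 rose. Potassium channel subunits rose in 10 and fell in 3 of 49 and did not pass (camera adjusted p = 0.0608), with a median of 0.07, or -0.04 with rescaled libraries. Calcium channel subunits, SNAREs, GABA-A receptor subunits, ionotropic glutamate receptor subunits and kinesins did not pass either (camera adjusted p = 0.114, 0.0799, 0.285, 0.834 and 0.834).

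Non-coding genes made up 63 of 354 lower calls with a known biotype (17.8%) and 36 of 691 higher calls (5.21%; Fisher's exact p = 2.38e-10, two-sided), against 20.1% of the genes tested. Genes are not independent replicates. Without forebrain 1 the shares were 46 of 428 and 47 of 590 (Fisher's exact p = 0.152), so that the ratio between them fell from 3.42 to 1.35, and without forebrain 4 it was 3.88. Without midbrain 1 it was 1.96, and without midbrain 1, forebrain 1 and forebrain 4 it was 1.47 (46 of 332 and 53 of 564).

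The fullest 1 Mb window held 3 midbrain-only and 6 forebrain-only regions, equal to the medians over 1000 random draws. Midbrain ATAC library 3 had a median peak width of 507 bp and 3.76% of its peaks on chromosome X, where the other 5 standard libraries had 2.42% to 2.83%.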
